A study of Homo sapiens with 6 samples.

How the data were processed

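ZNF768, a zinc finger protein, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with a monoclonal antibody, per the labels, in 2 established human cell lines. Raji is a B cell line derived from a Burkitt lymphoma, and U2OS is an osteosarcoma line. The labels list 6 samples: 2 ZNF768 libraries and 1 input (chromatin without antibody) per line. Peak lists of the 4 ZNF768 libraries were used, and the 2 inputs were not analysed here. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether the replicates were separate cultures, so the spread between libraries may be technical. Only the exact permutation and sign-flip tests between lines use that spread. The other p-values come from shuffled positions, random lists, or counts of genes, peaks or chromosomes, and do not measure it.

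Reads were aligned to GRCh38 with BWA, per the submitters' processing notes. The peak caller, its threshold, read filters and the use of the input are not given in the sources used here. The authors deposited 1 list per library, so replicates had not been pooled. Every interval is 201 bp wide, and its middle base was taken as the peak centre. The authors' score, deposited for each peak, ranges from 21 to 3659.6 over the 4 lists and its scale differs between libraries. Its unit is not given in the sources used here, and between 91.1% and 96.0% of the values in a list are whole numbers. A deposited second score was a linear rescaling of the first to within 1.03 and was not used further. Scores served only to rank peaks, as a percentile within a list or within a set of regions common to the lists. Sequencing depth is unknown, and the precision of a share is given as a 95% Wilson interval, which covers counting error only. A position absent from a list is a position without a called peak and is not shown to be unbound.

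Coordinates are given on GRCh38, counted from 1. Gene names, biotypes and limits came from a RefSeq gene table of GRCh38.p14, of which 20037 protein-coding genes on chromosomes 1 to 22, X and Y were used. That table gives neither strand nor exons. The planned promoter class (around the transcription start) was therefore replaced by "gene end", meaning within 1 kb of either limit of a protein-coding gene, and exons were not separated from introns. The planned flank of 5 kb upstream of a gene likewise became 5 kb on either side, and the nearest transcription start became the nearest gene end. No genome sequence was used, so the planned analyses of the ZNF768 motif, of MIR-like sequence, of bound genomic motif sites and of peaks with a motif were not run.

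Peaks were called overlapping when they shared at least 1 bp. Chance overlap and chance location came from 100 shuffles of each list with bedtools 2.31.1 within its chromosomes, between the first and the last annotated gene. Assembly gaps, which the plan left out of the shuffles, could not be excluded without a genome sequence. The permutation p over shuffled positions is one-sided on the side of the observed value, and 0.0099 is the smallest that 100 shuffles can give. As a second background, chosen after seeing the data, every peak was displaced by 10 to 100 kb. A replicated region of a line merged overlapping peaks of both replicates. It was called shared when it overlapped a replicated region of the other line, and line-restricted when neither library of the other line had a peak within 500 bp. A gene was assigned a region whose centre lay in the gene or within 5 kb of it.

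Gene lists were fixed before the data were examined: 70 B cell genes, 70 mesenchymal or bone genes, 50 liver genes and 50 neuron genes as control lists, and ZNF768 with the 6 Elongator genes. All members were found in the gene table. Each of the 4 cell type lists was tested in 2 ways. Fisher's exact test (two-sided) compared its share among genes with Raji-restricted regions alone and among genes with U2OS-restricted regions alone. The share of its members with a restricted region was also set against 10000 random lists, each member replaced by 1 of the 200 non-members closest in length, with a two-sided permutation p of which 0.0002 is the smallest possible. Benjamini-Hochberg adjustment covered the 4 lists in the first test and the 8 list and line pairs in the second. Genes and regions are not replicates, so these p-values describe the peak lists. With 2 libraries per line, an exact two-sided permutation test between lines cannot give a p below 0.333.

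Named genes followed a rule fixed before the data were examined. It took the 10 protein-coding genes with the best mean score percentile among those with a peak of all 4 libraries at the same end, the 10 best regions restricted to each line, up to 6 members of each list with a restricted region, and ZNF768 with the Elongator genes. A region outside genes was named by the nearest gene end. Overlap, location, region and gene list steps were tested on simulated data: 500 planted Raji-restricted regions were recovered as 502, a planted overlap of 60% as 60.1%, and 5% of 100 null lists of 70 genes passed an unadjusted threshold of 0.05. Alternatives covered the better-scoring 50% of each list, the same number of best peaks (4540) from each list, other overlap and distance limits, all annotated genes, and leaving out each library. In shortened lists, line-restricted was judged against the kept peaks alone, so such a region may have a lower-ranked peak of the other line. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.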

Results

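The data were 4 lists of ZNF768 peaks, 2 from Raji B cells and 2 from U2OS osteosarcoma cells. Raji replicate 1 held 16000 peaks and Raji replicate 2 held 9348. U2OS replicate 1 held 9032 peaks and U2OS replicate 2 held 4540. Peaks covered between 0.913 Mb and 3.22 Mb per library. The round total of 16000 in the longest list may be a limit set by the submitters, which the sources used here do not settle. The study's title links ZNF768 to MIR elements, a family of ancient mammalian retrotransposons, and to expressed genes. The comparisons below concern where ZNF768 peaks lay in each line and which of them the lines shared.

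The first comparison asked how far replicates and lines shared ZNF768 sites. Most peaks of each line's shorter list recurred in its longer list: 81.8% of Raji replicate 2 peaks (95% Wilson interval 81.1 to 82.6) overlapped a peak of Raji replicate 1, and 88.9% of U2OS replicate 2 peaks (87.9 to 89.7) overlapped one of U2OS replicate 1. Many sites were common to the B cell and the osteosarcoma line as well. Of U2OS replicate 2 peaks, 71.2% (69.9 to 72.5) overlapped Raji replicate 1 and 67.9% (66.5 to 69.2) overlapped Raji replicate 2. Shuffled lists overlapped by means of 0.0586% to 0.207%, and each of the 12 ordered pairs of libraries lay above all 100 shuffles (one-sided permutation p = 0.0099, the smallest that 100 shuffles can give).

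**Figure D1:**
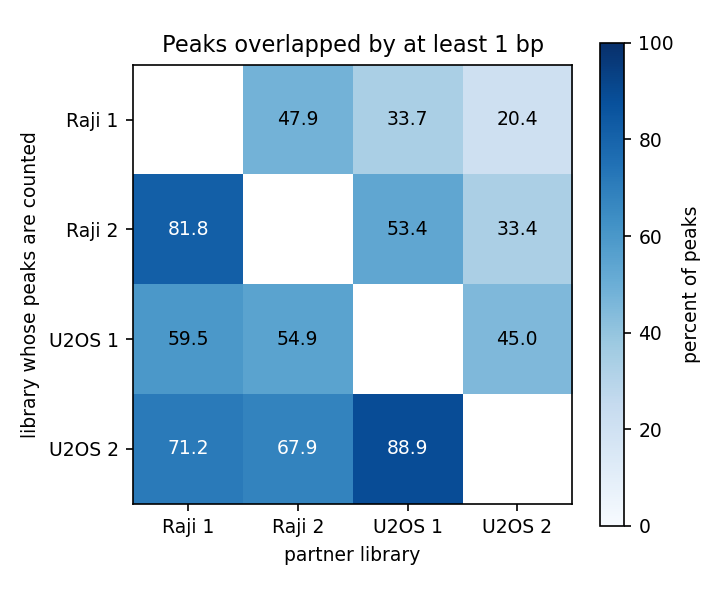
Percent of the peaks of each library (rows) that overlap a peak of another library (columns) by at least 1 bp. The highest shares, 88.9% and 81.8%, are those of the shorter list of each line in the longer list of the same line.

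Shares depended on the lengths of the lists, so they were also taken with 4540 best-scoring peaks from each library. Raji replicates then shared 67.0% (65.6 to 68.3) and 66.8% of their peaks, and U2OS replicates shared 69.9% and 70% of theirs. Between lines the shares ran from 32.0% (30.6 to 33.4) to 47.6% (46.2 to 49.1), below each within-line value. Positions agreed closely within and between lines, with a median distance between overlapping centres of 12 to 16 bp.

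Sites common to all libraries were ranked differently in each line. Over 2747 regions with a peak in all 4 libraries, the rank correlation of the authors' scores (Spearman, across regions, which are not independent replicates) was 0.86 between the Raji replicates and 0.86 between the U2OS replicates. Between a Raji and a U2OS library it was 0.27 to 0.32.

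**Figure D2:**
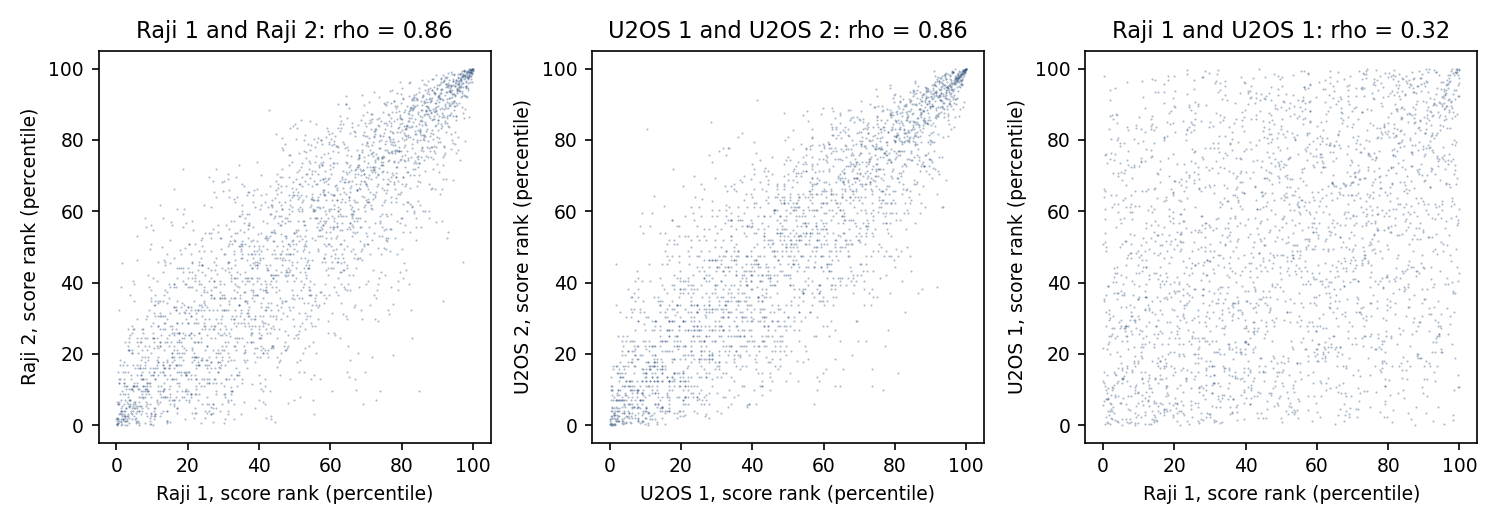
Each point is 1 of the 2747 regions with a peak in all 4 libraries, and both axes give its score rank as a percentile within the named library. Points follow the diagonal for replicates of a line (rho = 0.86 in each) and scatter widely between Raji replicate 1 and U2OS replicate 1 (rho = 0.32).

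The second comparison divided the replicated regions by line. Raji had 7540 regions with a peak in both replicates and U2OS had 4017. Of these, 2749 Raji regions overlapped a replicated U2OS region, which is 36.5% of the Raji and 68.4% of the U2OS regions. Raji-restricted regions numbered 3014 and U2OS-restricted regions 698. With 4540 best-scoring peaks per library the counts were 1356 and 1342, so the excess of Raji-restricted regions in the full lists was not seen between lists of equal length. At that setting a restricted region may have a peak of the other line that the cut removed, so the 2 settings do not count the same thing. Without Raji replicate 2 there were 15854 Raji regions and 10210 Raji-restricted ones, without U2OS replicate 1 there were 4649 Raji-restricted ones, and without U2OS replicate 2 there were 8983 U2OS regions, 3063 U2OS-restricted ones and 4405 shared Raji regions.

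The strongest Raji-restricted region lay inside ARID3A, which encodes a transcription factor first described in B cells, on chromosome 19 (947903 to 948108), with a mean score percentile of 99.8. Further top regions lay inside PRICKLE1 (chromosome 12, 42469378 to 42469685), inside the calcium channel gene CACNA1C (chromosome 12, 2187249 to 2187455) and inside the tetraspanin gene CD82 (chromosome 11, 44609119 to 44609332). Another lay 1.63 kb from an end of CSK, which encodes a kinase that restrains SRC family kinases, on chromosome 15 (74780348 to 74780549). The other 5 of the first 10 were nearest to TGS1, NEDD4L, SLC25A19, MAPKAPK2 and DNAJC5B, at 5.22 kb to 60.3 kb. The mean percentiles of these 10 regions were 99.5 to 99.8.

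The strongest U2OS-restricted region lay inside NCOR2, a nuclear receptor corepressor gene, on chromosome 12 (124519107 to 124519314), with a mean score percentile of 99.2. Others lay inside DHRS3, a retinal reductase gene (chromosome 1, 12596595 to 12596798), inside CHRNA3 (chromosome 15, 78619114 to 78619317) and 1.27 kb from ID1, which encodes an inhibitor of DNA-binding helix-loop-helix factors (chromosome 20, 31603917 to 31604117). Of the first 10 regions, 3 lay on chromosome 20 at 50.4 kb, 74.5 kb and 74.8 kb from CEBPB, a transcription factor gene and the nearest protein-coding gene. The remaining 3 were nearest to PARN, CRYBA4 and VAX1, at 28.5 kb to 477 kb.

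The third comparison concerned genes. ZNF768 peaks were enriched at the ends of protein-coding genes in both lines: 7.00% (6.61 to 7.41) of Raji replicate 1, 5.57% (5.13 to 6.06) of Raji replicate 2, 6.07% (5.59 to 6.58) of U2OS replicate 1 and 6.70% (6.005 to 7.46) of U2OS replicate 2 peaks lay within 1 kb of one. Shuffled lists gave 2.34% to 2.37%, so the enrichment was 2.95-fold, 2.35-fold, 2.56-fold and 2.86-fold (one-sided permutation p = 0.0099 in each library). Against peaks displaced by 10 to 100 kb, a background chosen after seeing the data that keeps the local gene density, it was 1.66-fold, 1.28-fold, 1.505-fold and 1.54-fold (one-sided permutation p = 0.0099 in each). In Raji replicate 2 that excess lay beyond 200 bp from gene ends: within 200 bp it had 0.856% of its peaks against 0.927% of displaced ones, where Raji replicate 1 was 2.68-fold above them. The lines did not differ measurably in this share, with means of 6.29% ± 1.01 (SD, n = 2) in Raji and 6.38% ± 0.445 (SD, n = 2) in U2OS, a difference of -0.0950 percentage points (exact two-sided permutation p = 1.0). The sign of that difference turned with equal numbers of peaks (1.06 points), with the better-scoring 50% of each list (0.613), within 5 kb of gene ends (1.04), without Raji replicate 2 (0.618) and without U2OS replicate 2 (0.219).

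Gene bodies held more of the Raji than of the U2OS peaks. Away from gene ends, 53.0% ± 0.262 (SD, n = 2) of Raji peaks and 44.6% ± 1.11 (SD, n = 2) of U2OS peaks lay inside protein-coding genes, against 39.5% to 39.6% of shuffled positions (one-sided permutation p = 0.0099 in each library). Both Raji libraries lay above both U2OS libraries, a difference of 8.42 percentage points with an exact two-sided permutation p = 0.333, the smallest that 2 against 2 libraries allow. Among replicated regions the share inside genes was 59.1% for Raji-restricted, 47.0% for shared and 38.7% for U2OS-restricted regions. The U2OS-restricted share lay near the level of shuffled positions. Displaced peaks, which keep the local gene density, were not used for gene bodies. The excess of each library over shuffled positions was therefore not separated from local gene density.

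At 190 protein-coding genes, all 4 libraries had a peak at the same gene end. The highest mean score percentile belonged to CHST12, a chondroitin sulfotransferase gene, where the region on chromosome 7 (2403003 to 2403224) lay 335 bp from the gene's lower coordinate and reached the 99.8th to 100.0th percentile in the 4 libraries. SLC38A10 followed on chromosome 17 (81295667 to 81295884), 468 bp from a gene end. DEPDC5, which encodes a subunit of the GATOR1 complex that restrains mTORC1, had its region on chromosome 22 (31754180 to 31754396) inside the gene, 320 bp from its limit. SLC2A1, the gene of the glucose transporter GLUT1, had one on chromosome 1 (42959038 to 42959250), which also falls in the divergent non-coding gene SLC2A1-DT. The next were the mitochondrial ribosomal protein gene MRPS5, CCDC69, IRF2BP1, the semaphorin gene SEMA4B, the importin gene KPNB1 and the dynein gene DNAI4, with mean percentiles of 98.5 to 99.3. The DNAI4 region also lies inside the neighbouring gene MIER1, so its assignment is uncertain.

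Neither line had a ZNF768 peak in or within 5 kb of the ZNF768 gene itself (chromosome 16, 30524004 to 30532477) in any of the 4 lists. Of the genes of Elongator, a complex that modifies wobble uridines of tRNA, ELP2 had 1 Raji-restricted region (chromosome 18, 36150064 to 36150301), which was absent with 4540 peaks per library. ELP3 and ELP6 had 1 peak each in Raji replicate 1 alone, and ELP1, ELP4 and ELP5 had none in any library.

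The fourth comparison asked whether the lines differed at genes typical of each. B cell genes held Raji-restricted ZNF768 regions far more often than other genes of their length: 25 of 70 members (35.7%) against a mean of 10.3% in length-matched lists (central 95% of lists 4.29% to 17.1%; permutation p = 0.0002, the smallest possible, adjusted p = 0.0016). No member held a U2OS-restricted region, against a matched mean of 1.86% (permutation test, adjusted p = 0.90). This does not mean that U2OS lacked peaks there. Replicated U2OS regions, restricted or not, lay at 12 members (17.1%, matched mean 9.66%), and all 12 also held a replicated Raji region. That count of all replicated regions was chosen after seeing the data. PLCG2, the phospholipase gene downstream of the B cell receptor, held 9 Raji-restricted regions, the best of them inside the gene on chromosome 16 (81821859 to 81822068) at a mean percentile of 98.5. Over PLCG2 there were 17 and 14 peaks in the Raji replicates and 4 in each U2OS replicate. The next members by percentile were ARHGDIB, a Rho inhibitor of blood cells (chromosome 12, 14956215 to 14956422), AFF3 (chromosome 2, 100113964 to 100114167), CD38 (chromosome 4, 15777728 to 15777942), the sialyltransferase gene ST6GAL1 (chromosome 3, 187013260 to 187013462) and LAPTM5 (chromosome 1, 30760829 to 30761029), with mean percentiles of 97.46, 96.6, 95.8, 93.5 and 89.1. The CD38 region lay outside the gene, 0.493 kb from its end, and the LAPTM5 region lay outside at 3.155 kb. Further members, named here after their values were seen, were the B lineage transcription factor genes EBF1 with 4 restricted regions and PAX5 with 3, the MHC class II activator gene CIITA with 5, the kinase gene BTK with 1 and the deaminase gene AICDA with 1. Replicated Raji regions, restricted or not, numbered 4 at EBF1, 6 at PAX5, 11 at CIITA, 1 at BTK and 1 at AICDA. With 4540 peaks per library, PAX5, CIITA and BTK held no restricted region, and 17 of the 25 genes still held one. Without Raji replicate 2 the share of the list was 64.3%, but the matched mean was also higher, at 26.0%.

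**Figure D3:**
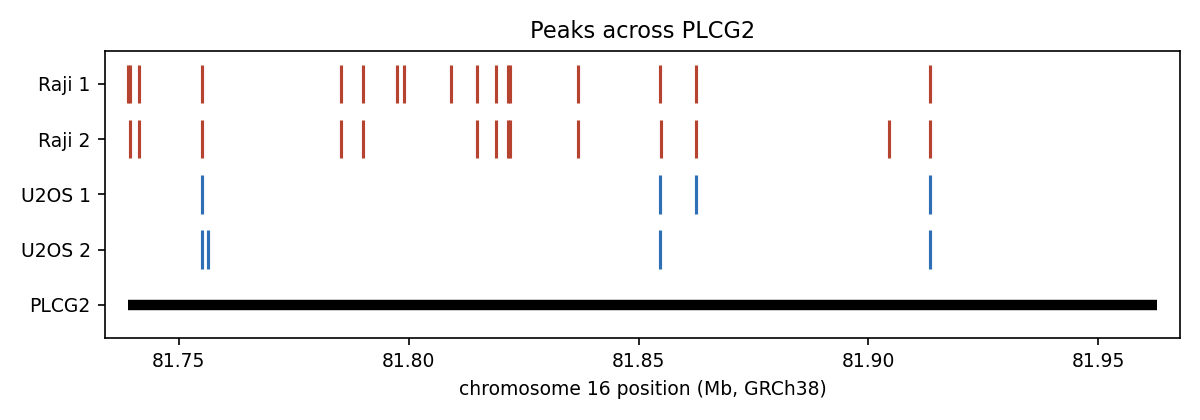
Peak centres of the 4 libraries across PLCG2 with 5 kb on each side, against the position on chromosome 16 in Mb; the black bar is the gene. Raji replicates have 17 and 14 peaks and U2OS replicates 4 each.

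Mesenchymal and bone genes showed no such excess in U2OS. U2OS-restricted regions lay at 3 of 70 members (4.29%, matched mean 1.80%, permutation test, adjusted p = 0.69), namely the integrin gene ITGA3 (chromosome 17, 50055496 to 50055699), the receptor gene EGFR (chromosome 7, 55065170 to 55065423) and the ephrin receptor gene EPHA2 (chromosome 1, 16145762 to 16145994). Raji-restricted regions lay at 6 members (8.57%, matched mean 10.8%, permutation test, adjusted p = 0.94), namely ALPL, AXL, TGFBR2, TWIST2, PDGFRB and LOXL2. Of 50 liver genes, 4 held a Raji-restricted region (8.00%, matched mean 7.47%, permutation test, adjusted p = 1.0), namely HNF4A, PAH, HPD and APOC3, and 0 held a U2OS-restricted one (matched mean 1.28%, adjusted p = 1.0). Of 50 neuron genes, 6 held a Raji-restricted region (12%, matched mean 16%, permutation test, adjusted p = 0.90) and 6 a U2OS-restricted one (12%, matched mean 3.83%, adjusted p = 0.086). The Raji-restricted ones lay at CNTNAP2, RBFOX3, UNC13A, SV2B, GAD2 and STX1A, and the U2OS-restricted ones at MAP2, RBFOX1, GRIN2B, CPLX2, RBFOX3 and CACNA1B. The U2OS share of the neuron list passed without Raji replicate 1 (16%, matched mean 5.12%, permutation test, adjusted p = 0.024). It also passed without U2OS replicate 2 (36%, matched mean 13.5%, permutation test, adjusted p = 0.00080).

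**Figure D4:**
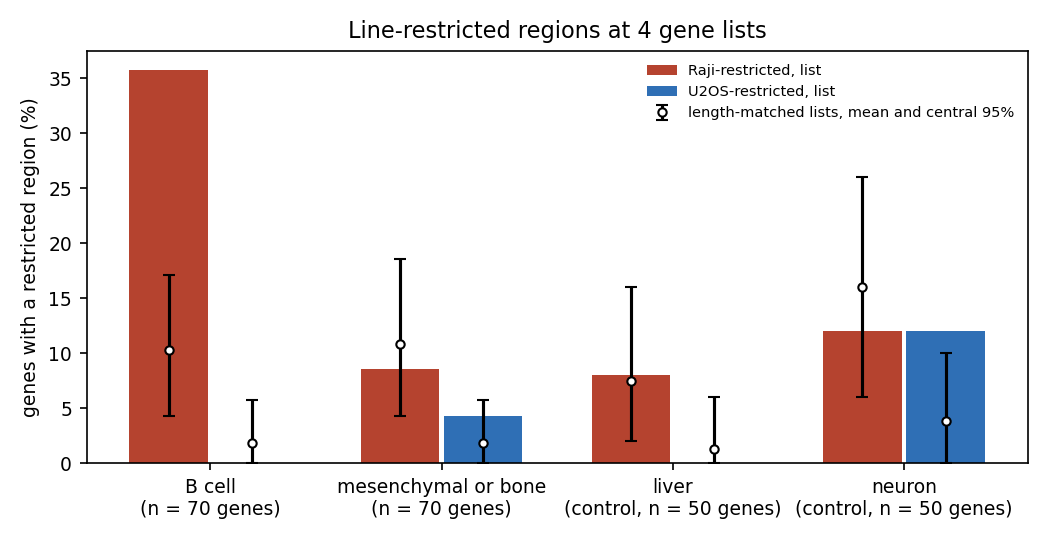
Percent of the genes of each list with a Raji-restricted or U2OS-restricted region (bars), with the mean and the central 95% of length-matched random lists (open circles and black lines). The B cell bar for Raji, 35.7%, lies above its matched range, which ends at 17.1%.

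Set directly against each other, the lines differed at the B cell list by less than the test could call. B cell genes were 25 of the 1783 genes with Raji-restricted regions alone (1.40%, 0.952 to 2.06) and 0 of the 266 with U2OS-restricted regions alone (upper Wilson bound 1.42%), with an adjusted p = 0.13 by Fisher's exact test. With 4540 best-scoring peaks per library, and restricted judged within those peaks alone, they were 20 of 817 and 1 of 512 (Fisher's exact test, adjusted p = 0.0038). Over all settings run the adjusted p of that test ranged up to 1.0. The difference also passed without U2OS replicate 2 (adjusted p = 0.020 in the exact test). In the exact test the mesenchymal list gave 6 and 3 genes (0.337% and 1.13%, adjusted p = 0.13), the liver list 4 and 0 (0.224% and 0%, adjusted p = 1.0) and the neuron list 5 and 5 (0.280% and 1.88%, adjusted p = 0.021). The neuron difference did not pass the exact test without Raji replicate 1 (adjusted p = 0.13) or without U2OS replicate 1 (0.053). Within 1 kb of gene ends alone, where few genes held a restricted region, 3 of 70 B cell genes held a Raji-restricted one (4.29%, matched mean 0.864%, central 95% of lists 0 to 2.86%). The share stayed above that range, with a permutation p = 0.044 that did not pass after adjustment (0.35).

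The last comparison was of chromosomes. Peaks of the U2OS libraries lay more often on chromosomes 16, 20 and 22 (means of 7.19%, 6.50% and 5.51%) than those of the Raji libraries (5.37%, 4.81% and 4.09%), and less often on chromosomes 3, 13 and 18 (4.48%, 0.840% and 0.773% against 5.94%, 1.56% and 1.34%). These 6 chromosomes were chosen after their values were seen. Both libraries of one line lay above both of the other on 13 of 23 chromosomes, and on 12 with 4540 best-scoring peaks per library. Chance gives 33.3% with 2 libraries per line if the libraries are exchangeable. Both Raji lists were longer than both U2OS lists, and shares of chromosomes depend on each other, so 33.3% is only a rough guide. The share of peaks that would have to move to equalise 2 distributions was 4.07 to 13.2 percentage points between libraries of different lines and 5.81 and 6.30 between replicates. The ranges overlapped in the full lists, where the lowest value, 4.07, was between Raji replicate 2 and U2OS replicate 1, which are close in length. With 4540 best-scoring peaks per library, a setting chosen after seeing the data, the values were 8.46 to 14.0 points between lines and 5.04 and 6.76 between replicates.

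**Figure D5:**
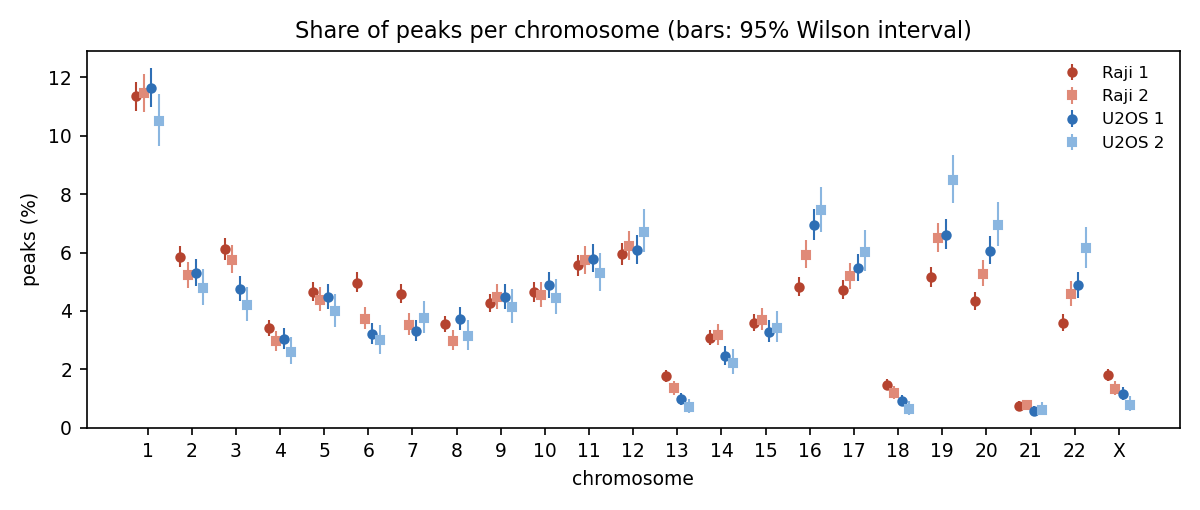
Percent of each library's peaks on chromosomes 1 to 22 and X, with 95% Wilson intervals. On chromosome 20 the Raji libraries have 4.34% and 5.28% and the U2OS libraries 6.07% and 6.94%.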

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

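The list length test for chromosome shares was chosen after the result was seen. The predictions of the other tests were written before theirs.

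One list differed between the lines in the direct test. Neuron genes made up 5 of the 1783 genes with Raji-restricted regions alone and 5 of the 266 with U2OS-restricted regions alone, a difference of -1.6 percentage points (Raji minus U2OS; Fisher's exact test, adjusted p = 0.021). The list had been fixed as a control, and its adjusted p ranged from 0.00050 to 1.0 over the settings run. It did not pass without Raji replicate 1 (0.13) or without U2OS replicate 1 (0.053).

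B cell genes held Raji-restricted regions at 35.7% against 10.3% in length-matched lists. The tables argue against a gene-dense setting, since the upper 2.5% limit of lists matched on length and on genes within 500 kb was 18.6%, and against more DNA of certain chromosomes, since that of lists matched on chromosome and length was 17.2%. With 4540 peaks per library, where restricted leaves out U2OS peaks that the cut removed, the share was 30.0% against a matched mean of 5.07%. That argues against the longer Raji lists as the whole cause. Unspecific pull-down at open chromatin stays open: the median distance between replicate centres at 51 such regions was 0.917 times that at shared regions (bootstrap 95% interval 0.667 to 1.33), but the planned limit on it was wrong, since these regions were chosen for overlapping peaks and no value here shows that unspecific peaks have wider centres. Copy number changes smaller than a chromosome also stay open, as does a candidate explanation not tested here, ZNF768 binding that follows the activity of genes of the line.

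Chromosome shares differed more between lines than within them with 4540 peaks per library, where the lowest between-line distance was 8.46 points and the highest within-line one 6.76. For those best peaks this argues against list length as the whole cause. In the full lists the distances overlapped. Raji replicate 2 and U2OS replicate 1, the lists of different lines closest in length (9348 and 9032 peaks), were 4.07 points apart, below both within-line values (5.81 and 6.30). List length as a cause of the distances between full lists therefore stays open. Over 23 chromosomes, the score rank of common regions (Raji minus U2OS) was set against the log2 ratio of chromosome shares in the full lists. Spearman rho was 0.41 (bootstrap 95% interval 0.0075 to 0.72, permutation p = 0.055) and Pearson r 0.37 (permutation p = 0.078), and r was 0.27 without the 2 chromosomes farthest from the median share ratio. The ratio can change with list length: with 4540 peaks per library it went from 0.69 to -0.13 on chromosome X and from -0.44 to -0.59 on chromosome 20. The correlation was not recomputed at equal length, so list length was not held alike in it. Rho missed the threshold while its interval reaches well above 0. A rho above 0 could come from chromosome-wide copy number or from a difference between the lines in the sites used. These cannot be told apart with either outcome of the test.

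Of the 8343 peaks of Raji replicate 1 without a partner in Raji replicate 2, 3.66% (3.27 to 4.08) were within 200 bp of a gene end, against 0.979% (0.782 to 1.23) of the 7657 with a partner. In Raji replicate 2 the shares were 0.354% (6 peaks) and 0.967%, while U2OS replicate 1 (1.73% and 1.18%) and U2OS replicate 2 (2.17% and 1.17%) ran as in Raji replicate 1 but by less, and the odds ratios pooled over score classes were 0.436 (0.176 to 1.08), 1.098 (0.707 to 1.70) and 1.51 (0.749 to 3.06), each with an interval that includes 1. Lower scores alone are argued against in Raji replicate 1, where the pooled odds ratio was 5.58 (95% interval 4.04 to 7.71). Unspecific pull-down at highly transcribed genes in that library may contribute: tRNA genes lay within 1 kb of peaks without a partner more often, with an odds ratio of 3.58 (1.69 to 8.47, Fisher's exact test p = 0.00022, 35 and 9 peaks). That ratio was not pooled over score classes, so lower scores were not held alike. In Raji replicate 2, U2OS replicate 1 and U2OS replicate 2 it was 0, 1.14 and 1.60, each with an interval that includes 1. Binding by ZNF768 that Raji replicate 2 did not recover, for a reason other than score, was not tested.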

How the results depend on the processing

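Displaced peaks as background, equal numbers of peaks for chromosomes and all replicated regions for gene lists were chosen after seeing the data. All 12 overlap shares stayed above chance, and the enrichment at gene ends kept its direction and threshold in all 4 libraries, under each setting run; overlap of 50% and centres within 100 bp are the same rule for peaks of this fixed width. Most region counts fell in shorter lists, but U2OS-restricted regions did not. In a shorter list, a restricted region may have a peak of the other line that the cut removed. With the better-scoring 50% of each list, replicated regions numbered 3966 in Raji and 2185 in U2OS, 1191 were shared, 2003 were Raji-restricted and 705 were U2OS-restricted; with 4540 peaks per library there were 2990 replicated Raji regions, 1233 shared, 1356 Raji-restricted and 1342 U2OS-restricted regions. Restricted regions in the better-scoring 50% of both replicates numbered 1355 and 284. Leaving out 1 library gave 7540 to 15854 replicated Raji regions, 4017 to 8983 in U2OS, 2836 to 4405 shared Raji regions, 2840 to 4414 shared U2OS regions, 3102 to 10210 Raji-restricted and 915 to 3063 U2OS-restricted regions; fewer lists then have to hold a region, or to lack it, so the counts cannot be read as stability. The Raji minus U2OS difference at gene ends changed sign, to 0.613 points with the better-scoring 50%, 1.06 with equal numbers and 1.04 within 5 kb, and ran from -0.808 to 0.618 without single libraries. Score ranks of same-numbered libraries did not deviate together (r = 0.033 between their deviations over 2747 regions). That check covers only regions called in all 4 libraries, so it cannot exclude a pairing that acts on the number of peaks. Replicate 1 had the longer list in both lines (16000 against 9348 and 9032 against 4540 peaks). The replicate block left the difference at gene ends at -0.0950 and that in gene bodies at 8.42 points (exact sign-flip p = 1.0 and 0.50, the smallest possible being 0.50). The direct B cell difference passed with the better-scoring 50% (2.04 points, exact test, adjusted p = 0.028), equal numbers (2.25), the nearest gene end within 50 kb (1.66) and without U2OS replicate 2 (1.02 to 1.26 points and adjusted p from 0.020 to 0.28 over the libraries left out). The B cell share in Raji was 4.29% at gene ends alone, above a matched mean of 0.864% that was lower too, and did not pass after adjustment with 3 genes. The B cell share in Raji was 35.7% to 64.3% without single libraries, against matched means of 10.5% to 26.0%, and passed each time. The direct neuron difference was -1.30 to -0.887 points without single libraries. It did not pass without Raji replicate 1 or U2OS replicate 1 or with all replicated regions (-0.894), and turned to 0.526 at gene ends alone. U2OS-restricted regions of neuron genes passed at 12% with the better-scoring 50%. Without single libraries they ranged from 12% to 36%, against matched means of 4.53% to 13.5%. Shares that changed side of their matched mean without passing were, for U2OS at B cell genes, 2.86% without Raji replicate 1 (range 0 to 7.14% over the libraries left out, the others keeping their side) and 17.1% with all replicated regions; for Raji at mesenchymal genes, 12.9% by nearest end and 20.0% with all replicated regions; for Raji at liver genes, 4.00% (better-scoring 50%), 2.00% (equal numbers), 8.00% to 16% (single libraries left out, the side kept only without U2OS replicate 2), 0% (gene ends), 6% (nearest end) and 14.0% (all replicated regions); for U2OS at liver genes, 2.00% (nearest end); and at neuron genes, 24.0% for Raji without Raji replicate 1 (range 12% to 24.0%, the others keeping their side), 2.00% for Raji and 0% for U2OS at gene ends. The direct liver difference turned to -0.130 points by nearest end. Without single libraries it was 0.0506 to 0.181 points, against 0.224 with all libraries. The direct mesenchymal difference was -0.621 to -0.169 points without single libraries, against -0.791 with all of them, and did not pass. The causes were not tested. Of 71 named regions and list members, 48 kept their line-restricted status with equal numbers and 52 with the better-scoring 50%; of the 25 B cell genes, 17 and 21 did. Fewer lists can only add restricted regions, so leaving out a library does not test the named ones. Families and gene classes were not recomputed under the alternatives. The mean chromosome distance between lines was 8.59 points and 11.7 with equal numbers. The motif settings, bound motif sites and chromosome shares of peaks with a motif were not run, since no genome sequence was used. Depth is unknown and limits what an absent peak can show.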

Other observations

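Gene families were examined after the files had been seen, by symbol patterns and with the same length matching (permutation p, Benjamini-Hochberg adjusted over 12 family tests). Olfactory receptor genes, which are silent in most tissues, held few replicated ZNF768 regions: 7 of 392 (1.79%) in Raji against a matched mean of 6.52%, and 0 of 392 in U2OS against 3.56% (permutation test, adjusted p = 0.00048 in each). Zinc finger genes with ZNF symbols were also low, at 39 of 517 (7.54%, matched mean 16.8%) in Raji and 16 of 517 (3.09%, matched mean 8.52%) in U2OS (permutation test, adjusted p = 0.00048 in each). Genes with RPL or RPS symbols lay at their matched level, with 10 of 97 (10.3%, matched mean 10.3%) in Raji and 5 of 97 (5.15%, matched mean 5.37%) in U2OS (permutation test, adjusted p = 1.0 in each). That pattern takes in ribosomal S6 kinase genes beside ribosomal protein genes, so it does not describe ribosomal protein genes alone. SLC transporter genes did not differ either, at 70 of 386 (18.1%, matched mean 18.5%) and 36 of 386 (9.33%, matched mean 9.12%; permutation test, adjusted p = 1.0 in each). HOX genes had 0 of 40 in Raji (matched mean 7.98%, permutation test, adjusted p = 0.11) and 3 of 40 in U2OS (matched mean 4.13%, adjusted p = 0.67). Protocadherin genes reached 22 of 66 in both lines (permutation test, adjusted p = 0.077 in Raji and 0.00048 in U2OS), but all 22 counts came from 1 region in each line under overlapping genes. Members of a family lie side by side and can share regions, so these p-values are too small where they do. Matching was on length alone and read filters are unknown, so how uniquely reads align to a family was not held alike. Why a family was low was not tested.

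Other classes of genes were set against displaced peaks, also after the files had been seen. Peaks lay within 1 kb of the ends of pseudogenes less often than displaced peaks in all 4 libraries, at ratios of 0.569 and 0.593 in Raji and 0.526 and 0.493 in U2OS (one-sided permutation p = 0.0099 in each). How uniquely reads align at pseudogenes was not held alike in that comparison. Ends of long non-coding RNA genes were enriched at ratios of 1.46 and 1.30 in Raji and 1.47 and 1.5 in U2OS (one-sided permutation p = 0.0099 in each). For tRNA genes the ratios were 4.73, 2.51, 4.11 and 4.05, resting on 44, 9, 12 and 6 peaks (one-sided permutation p = 0.0099, 0.020, 0.0099 and 0.0099). No difference was detected for miRNA genes, at ratios of 1.11, 0.953, 0.713 and 1.03 (one-sided permutation p from 0.14 to 0.53), or for snoRNA genes, at ratios of 0.636, 0.868, 0.973 and 0.686 (one-sided permutation p from 0.079 to 0.51).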
